A study of Mus musculus with 7 samples.

How the data were processed

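RNA was measured in 7 brains of newborn C57BL/6 mice at postnatal day 0, 4 wild type and 3 heterozygous Setd2SRI/wt. Per the labels, total RNA (100 ng) was depleted of ribosomal RNA, made into stranded libraries and sequenced as 2 × 76 bp read pairs on a NextSeq 500, with about 20 M reads (M, 1e6) per sample. The authors deposited a table of raw gene counts, and the names they give for its processing are FastQC, Trim Galore, HISAT2, featureCounts and edgeR on the mm10 genome. The versions, the strand setting and the handling of reads with several matches were not given in the sources used here. The deposited counts were whole numbers for 55536 Ensembl genes, all with the same identifier and symbol as GENCODE mouse release 21, and 21951 of them had no count in any library. Counts of genes that overlap other genes are uncertain because the strand setting is not stated.

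Total counts ran from 4192021 to 16064644 per library, and 22368 to 27411 genes were detected. Within a genotype the chi-square per degree of freedom between libraries ran from 3 to 14.7, so the spread between animals exceeded counting error. Samples were grouped by the genotype and sex in their titles. The labels describe littermates and do not say which animals shared a litter, so no litter term was used. The column name of 1 mutant library differed slightly from its sample title and was matched as the one mutant male.

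Genes were filtered with filterByExpr, scaled by TMM and tested two-sided with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with genotype and sex in the model. P-values were adjusted by Benjamini-Hochberg and called under 0.05. The same model gave the sex comparison, and a model with the product of genotype and sex gave the interaction. Fold changes are Setd2SRI/wt over wild type, or male over female, on the log2 scale. Their SE was computed as the absolute log2 fold change divided by the square root of the F statistic. It thus restates the F-test and is no separate measure of spread. CPM values were scaled by TMM, except for the markers of hindbrain, pituitary and olfactory tissue, which are CPM of the total count.

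Altogether 40 gene lists of cell types, brain regions, cell states and gene families were fixed in advance, and the 36 with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2). The correlation between genes was preset to 0.01, and as an alternative it was estimated for each list. Members were also adjusted over the list alone. An exact permutation test of the mean list difference used the 35 splits of 7 libraries into 4 and 3. The genes named were fixed by rule: genes past the threshold with a mean CPM of at least 1, up to 10 per direction, filled up to 10 with the smallest p-values, plus Setd2, and from each list the gene of smallest p with up to 3 more where the list passed. For sex, up to 5 genes per direction and the Y-linked list were named. Other genes named from lists are among those that passed adjusted over the list alone, and the values of some list members are not reported here. The comparisons, tests, gene lists, rule for names and most alternatives were chosen before the data were examined.

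The alternatives were DESeq2 size factors, total counts, TMM without abundant gene classes, no filter, a mean CPM of at least 1, the Wald test of DESeq2 1.42.0, limma-voom, robust dispersion, an adjusted p under 0.1, leaving out each library in turn, no sex term, females only with and without a replicate block, and wild type only for sex. For the lists they also included fry. Thinning all libraries to the depth of the shallowest and leaving out the 2 libraries with pituitary transcripts were chosen after seeing the data. The model was tested on simulated data with the depths and dispersions of these libraries in 5 rounds of 17260 genes. For genotype, edgeR recovered 47.2% of genes changed 1.5-fold and 79% of genes changed 2-fold, and 7.07% of its calls were false. DESeq2 recovered 46% and 75.8%, with 5.43% false. For sex, edgeR recovered 43.6% and 80.6% with 6.33% false. A simulated list of 12 genes shifted 1.5-fold was found in 5 of 5 rounds with the preset correlation, with 1 false list, and in 3 of 5 with an estimated correlation, with 0 false lists. The genes were simulated independently, so these rounds do not show how often the preset correlation gives false lists when genes are correlated. For single genes, the changed ones had a mean CPM of at least 1, with 500 at each fold over the 5 rounds. Many true changes loosen the adjusted threshold, and no difference in tissue share was simulated. The recovered and false shares therefore need not hold for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.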

Results

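RNA was sequenced from the brains of newborn C57BL/6 mice at postnatal day 0. Wild-type animals were compared with littermates heterozygous for a Setd2 allele with the R2483H change in the SRI domain, written Setd2SRI/wt. Setd2 encodes the methyltransferase that trimethylates histone H3 at lysine 36 during transcription, and the SRI domain is the part of the protein that binds RNA polymerase II. There were 7 libraries, 4 from wild-type brains (2 males and 2 females) and 3 from Setd2SRI/wt brains (1 male and 2 females). The values were gene counts for 55536 Ensembl genes. Total counts were 15924237 in wild-type male 1, 4192021 in wild-type male 2, 16064644 in wild-type female 1 and 14838099 in wild-type female 2. They were 5538908 in the Setd2SRI/wt male, 6580814 in Setd2SRI/wt female 1 and 12896134 in Setd2SRI/wt female 2. The labels do not say which animals shared a litter, so the p-values measure the spread between these libraries. Between any pair of libraries the correlation of log2 CPM (counts scaled to the library total) lay between 0.9727 and 0.9893, and the common biological coefficient of variation was 12.2%.

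The first comparison asked how the heterozygous Setd2 change alters gene expression in the newborn brain. Setd2 itself (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633, mm10) had 103.5 ± 6.72 CPM (SD, n = 4) in wild type and 96.9 ± 17.9 CPM (SD, n = 3) in Setd2SRI/wt. Its log2 fold change was -0.14 ± 0.11 (SE) with an adjusted p of 0.798 in edgeR. The Setd2 value was -0.047 without the Setd2SRI/wt male, -0.09 without Setd2SRI/wt female 1 and -0.25 without Setd2SRI/wt female 2, and over the alternatives its adjusted p ran from 0.329 to 1. A missense allele need not change the level of its mRNA, so this value does not check the genotype labels.

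Slc17a6 and Ret were lower and Robo3 was higher in the Setd2SRI/wt libraries. Counts were taken over all cells of a sample. A different share of brain regions and a different expression within them therefore cannot be told apart for these genes. Slc17a6, the vesicular glutamate transporter typical of subcortical excitatory neurons, had 134 ± 11.2 CPM (SD, n = 4) in wild type and 76.6 ± 13.6 CPM (SD, n = 3) in the mutants, with a log2 fold change of -0.84 ± 0.12 (SE) and an adjusted p of 0.0295. Ret, the receptor of GDNF family ligands, had 28.2 ± 8.47 CPM in wild type and 10.1 ± 2.44 CPM in the mutants, a log2 fold change of -1.36 ± 0.21 (SE, adjusted p = 0.0462). Robo3, an axon guidance receptor of commissural neurons, had 28.0 ± 3.88 CPM in wild type and 47.4 ± 8.53 CPM in the mutants, a log2 fold change of 0.80 ± 0.12 (SE, adjusted p = 0.0462). For each of these 3 genes, all 3 mutant libraries lay on one side of all 4 wild-type libraries. The same held for 1366 genes in all, 7.91% of those tested, against 5.71% expected by chance. In mm10, Slc17a6 (ENSMUSG00000030500) lies on chromosome 7 from 51622006 to 51671119, Ret (ENSMUSG00000030110) on chromosome 6 from 118151745 to 118197718 and Robo3 (ENSMUSG00000032128) on chromosome 9 from 37415669 to 37433246, and none of the 3 overlaps another annotated gene.

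These were the 3 genes that passed among 17260 tested, and 1545 genes had an unadjusted p under 0.05, 663 of them higher and 882 lower in the mutants. DESeq2 called 65 genes, Slc17a6, Ret and Robo3 among them, and limma-voom called 1, Slc17a6. With total counts or a mean CPM of at least 1, edgeR called Slc17a6 alone, and with robust dispersion it called Slc17a6, Robo3 and Irx2 but not Ret. With no sex term it called 0 genes, with 1393 at an unadjusted p under 0.05, and in females alone, without a replicate block, none of the 3 was called.

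Each of the 3 calls was lost when any one of 5 libraries was left out, namely wild-type male 1, wild-type male 2, wild-type female 2, the Setd2SRI/wt male or Setd2SRI/wt female 2. The log2 fold changes without them ranged from -0.87 to -0.78 for Slc17a6, from -1.38 to -1.10 for Ret and from 0.72 to 0.79 for Robo3. With these libraries left out in the order given, 2, 0, 0, 1 and 1 genes were called. Without wild-type female 1, 110 genes were called, and without Setd2SRI/wt female 1, 11 genes, with Slc17a6, Ret and Robo3 among them each time.

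**Figure D1:**
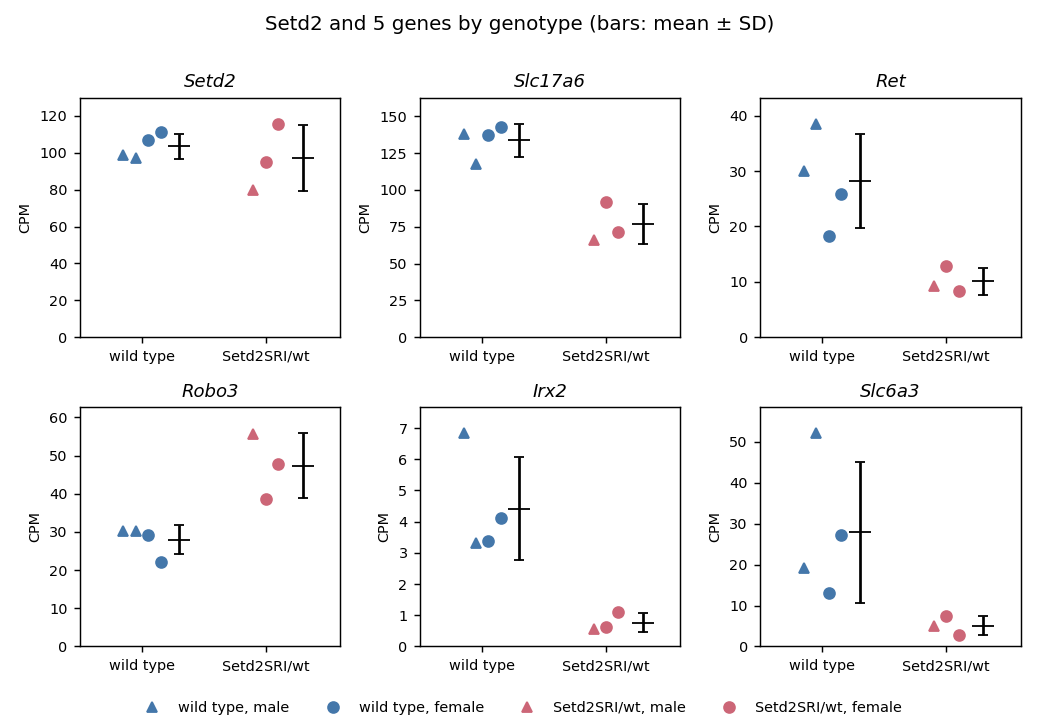
CPM of Setd2, Slc17a6, Ret, Robo3, Irx2 and Slc6a3 in each library, by genotype, with triangles for males, circles for females and black bars for the mean ± SD (n = 4 wild type, n = 3 Setd2SRI/wt). The mutant libraries lie at 66.1 to 92.0 CPM for Slc17a6 and the wild-type libraries at 117 to 142 CPM, while the Setd2 values of the groups overlap.

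The genes next in rank did not pass. Irx2, a homeobox gene, had 4.42 ± 1.66 CPM in wild type and 0.756 ± 0.305 CPM in the mutants (log2 fold change -2.34 ± 0.38, SE, adjusted p = 0.0626). Slc6a3, the dopamine transporter, had 27.9 ± 17.2 and 5.08 ± 2.38 CPM (log2 fold change -2.32 ± 0.39, SE, adjusted p = 0.0783). Zdbf2, Klhl1, Chrna6, Lhx1, C130021I20Rik and BC035947 had log2 fold changes of -0.78, -1.21, -2.38, -2.02, -2.55 and -1.50, each with an adjusted p of 0.112. With higher values in the mutants, the mitochondrial tRNA gene mt-Tp and Rnf112 had log2 fold changes of 0.77 and 0.52 with an adjusted p of 0.112. The forebrain synaptic genes Ddn and Nrgn, the latter encoding neurogranin, had log2 fold changes of 0.51 and 0.55, and Pamr1 one of 0.60, with an adjusted p of 0.132. Rasgef1b, Hpca, Sept5 and C730002L08Rik followed with log2 fold changes of 0.54, 0.49, 0.51 and 0.83 and adjusted p-values of 0.141, 0.147, 0.163 and 0.166. Zdbf2, BC035947, Ddn, Hpca, Sept5 and C730002L08Rik overlap other annotated genes, so their counts are uncertain.

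By camera with a preset correlation, gene lists of subcortical regions were lower in the mutant brains and a list of cortical identity genes was higher, and none of these calls held with an estimated correlation. The monoamine neuron list had a median log2 fold change of -1.46 over 9 tested genes (adjusted p = 5.09e-05 by camera, and adjusted p = 0.616 with an estimated correlation). Of its members 0 passed over all genes and 7 adjusted over the list alone, Slc6a3, Slc18a2, Ddc, Th, Slc6a4, Lmx1b and Dbh. Slc18a2, the vesicular monoamine transporter, had 25.9 ± 9.11 CPM in wild type and 10.8 ± 0.600 CPM in the mutants, and Th, tyrosine hydroxylase, had 23.5 ± 12.5 and 8.02 ± 4.74 CPM. Slc6a4 and Dbh had group means of at most 1.03 CPM. Without wild-type female 2, a library with pituitary transcripts, the list's median was -0.82 (adjusted p = 0.00801), and without both libraries with such transcripts it was -0.97 (adjusted p = 0.00163).

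The cerebellum list had a median log2 fold change of -0.77 over 10 genes (adjusted p = 0.00182, and adjusted p = 0.4931 with an estimated correlation). In it 0 genes passed over all genes and 6 adjusted over the list alone, Cbln1, Zic1, Pcp2, En1, Zic2 and Barhl1. Cbln1, a synapse organiser secreted by granule cells, had 28.2 ± 7.38 CPM in wild type and 18.0 ± 6.35 CPM in the mutants, and the transcription factor gene Zic1 had 66.7 ± 11.5 and 44.6 ± 14.3 CPM. The thalamus list had a median of -0.41 over 8 genes (adjusted p = 0.00265, and adjusted p = 0.707 with an estimated correlation), with 0 members passing over all genes and 4 adjusted over the list alone, Lhx9, Tcf7l2, Slc6a4 and Gbx2. Tcf7l2, a regulator of thalamic neurons, had 41.0 ± 11.02 and 28.7 ± 5.11 CPM. Slc6a4 stood in both the monoamine and the thalamus list. The thalamus median was -0.20 without wild-type female 1 (adjusted p = 0.032), -0.25 with a mean CPM of at least 1 (0.0093) and -0.27 with no sex term (0.0167).

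The hypothalamus list had a median of -1.16 over 11 genes (adjusted p = 0.0064, and adjusted p = 0.882 with an estimated correlation), with 0 members passing over all genes and 6 adjusted over the list alone, Sim1, Otp, Trh, Gal, Oxt and Pmch. Its wild-type values differed widely, and the highest came from a library with pituitary transcripts. Sim1, a transcription factor gene of hypothalamic neurons, was at 9.10 CPM in wild-type female 2 and between 1.44 and 2.14 CPM in the other wild-type libraries, against 0.580 ± 0.171 CPM (SD, n = 3) in the mutants. Without wild-type female 2 the list's median was -0.49 (adjusted p = 0.0404). Without Setd2SRI/wt female 2 its call was lost (adjusted p = 0.149).

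The cortex and hippocampus identity list had a median of 0.27 over 8 genes (adjusted p = 0.0183, and adjusted p = 0.4931 with an estimated correlation). In it 0 genes passed over all genes and 5 adjusted over the list alone, among them Lhx2, Emx1 and Bhlhe22 higher and Zbtb20 lower. Lhx2, a patterning gene of the cortex, had 42.8 ± 5.07 CPM in wild type and 57.6 ± 8.93 CPM in the mutants. The call of the list was lost without wild-type female 2 (adjusted p = 0.0547) and without Setd2SRI/wt female 2 (adjusted p = 0.0841), and in females alone (adjusted p = 0.0697). The excitatory neuron list did not pass (adjusted p = 0.0599). In it 1 gene, Slc17a6, passed over all genes and 4 adjusted over the list alone. Among these the cortical genes Neurod6, Tbr1 and Slc17a7 had positive log2 fold changes of 0.42, 0.36 and 0.35, and Slc17a6 a negative one.

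Clustered protocadherins, cell adhesion proteins that give neurons individual surface identities, were lower in the mutants, with a median log2 fold change of -0.36 over 54 genes, 48 of them negative (adjusted p = 1.04e-13 by camera, and adjusted p = 0.4931 with an estimated correlation). In the list 0 genes passed over all genes and 2 adjusted over the list alone, Pcdhb2 and Pcdhgb6. Pcdhb2 had 3.65 ± 1.03 CPM in wild type and 1.46 ± 0.519 CPM in the mutants, and Pcdhgb6 had 13.6 ± 1.66 and 8.55 ± 2.34 CPM. Pcdhgb6 shares exons with the other Pcdhg genes, so its count is uncertain, while Pcdhb2 overlaps no annotated gene. The list's deviation from the mean of all libraries was -0.514 in the Setd2SRI/wt male, -0.05 and -0.005 in the mutant females and 0.059 to 0.201 in wild type. Without the Setd2SRI/wt male the median was -0.226 (adjusted p = 0.00165), and in females alone it was -0.225 (0.00155).

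The glucocorticoid-induced list was lower, with a median of -0.23 over 11 genes (adjusted p = 0.00124, and adjusted p = 0.744 with an estimated correlation). In it 0 genes passed over all genes and 5 adjusted over the list alone, Sgk1, Errfi1, Tsc22d3, Per1 and Pdk4. Sgk1, a kinase gene induced by corticosteroids, had 173 ± 32.7 CPM in wild type and 81.2 ± 36.9 CPM in the mutants. The call was lost without the Setd2SRI/wt male (adjusted p = 0.186, median -0.23) and in females alone (adjusted p = 0.221, median -0.23). The median was -0.48 with no sex term, -0.43 without the libraries with pituitary transcripts, -0.10 without wild-type female 1, -0.44 without wild-type female 2, -0.40 without Setd2SRI/wt female 1 and -0.57 without Setd2SRI/wt female 2.

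The meninges and fibroblasts list had a median of -0.22 over 11 genes (adjusted p = 0.0352, and adjusted p = 0.91 with an estimated correlation), with 0 genes passing over all genes and 0 adjusted over the list alone. Its call was lost without wild-type male 2 (adjusted p = 0.0652), wild-type female 1 (0.174) or Setd2SRI/wt female 2 (0.564, median -0.105), and its median was -0.38 without Setd2SRI/wt female 1 and -0.377 without the libraries with pituitary transcripts. It was also lost after thinning all libraries to the depth of the shallowest (adjusted p = 0.0644).

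Cytosolic ribosomal protein genes were higher by a small amount, with a median of 0.10 over 78 genes, 74 of them positive (adjusted p = 3.53e-04, and adjusted p = 0.92 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Rps14 had 93.8 ± 8.77 and 117 ± 10.1 CPM. The call was lost without the Setd2SRI/wt male (adjusted p = 0.429, median 0.0202) and without Setd2SRI/wt female 1 (0.367, median 0.0256), and the median was 0.225 without Setd2SRI/wt female 2. It was also lost in females alone (adjusted p = 0.464, median 0.023) and without the libraries with pituitary transcripts (0.343, median 0.0237).

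The synaptic vesicle and scaffold list had a median of 0.10 over 22 genes (adjusted p = 0.0412, and adjusted p = 0.91 with an estimated correlation), with 0 genes passing over all genes and 1, Stx1a, adjusted over the list alone. Stx1a, a membrane protein of vesicle fusion, had 130.5 ± 3.52 CPM in wild type and 170.3 ± 10.8 CPM in the mutants. The call was lost without wild-type female 1 (adjusted p = 0.0913), wild-type female 2 (0.298, median 0.0508), Setd2SRI/wt female 1 (0.162) or Setd2SRI/wt female 2 (0.345, median 0.0646), and the median was 0.199 without the Setd2SRI/wt male and in females alone. It was also lost after thinning (adjusted p = 0.0645) and without the libraries with pituitary transcripts (0.402, median 0.0241).

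Altogether 10 of 36 tested lists passed by camera, 3 higher and 7 lower, and 0 of the 10 passed with an estimated correlation or by directional fry. An exact two-sided permutation test of the mean list difference over the 35 splits of the libraries, adjusted over the lists, gave 0.257 at the lowest. The smallest unadjusted exact p that this design allows was 0.0286, reached by protocadherins, cerebellum, thalamus and cortex and hippocampus identity. With this floor and 36 lists, an adjusted exact p under 0.05 was all but out of reach, so the adjusted exact values cannot decide. Over the alternatives run for the lists the adjusted p ran from 5.98e-08 to 0.616 for monoamine neurons, 6.74e-05 to 0.4931 for cerebellum, 2.95e-04 to 0.707 for thalamus, 5.52e-06 to 0.882 for hypothalamus, 0.016 to 0.4931 for cortex and hippocampus identity. It ran from 4.87e-16 to 0.4931 for protocadherins, 5.98e-07 to 0.744 for glucocorticoid-induced genes, 0.0031 to 0.91 for meninges, 6.59e-17 to 0.92 for ribosomal proteins, 8.35e-04 to 0.91 for synaptic genes.

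**Figure D2:**
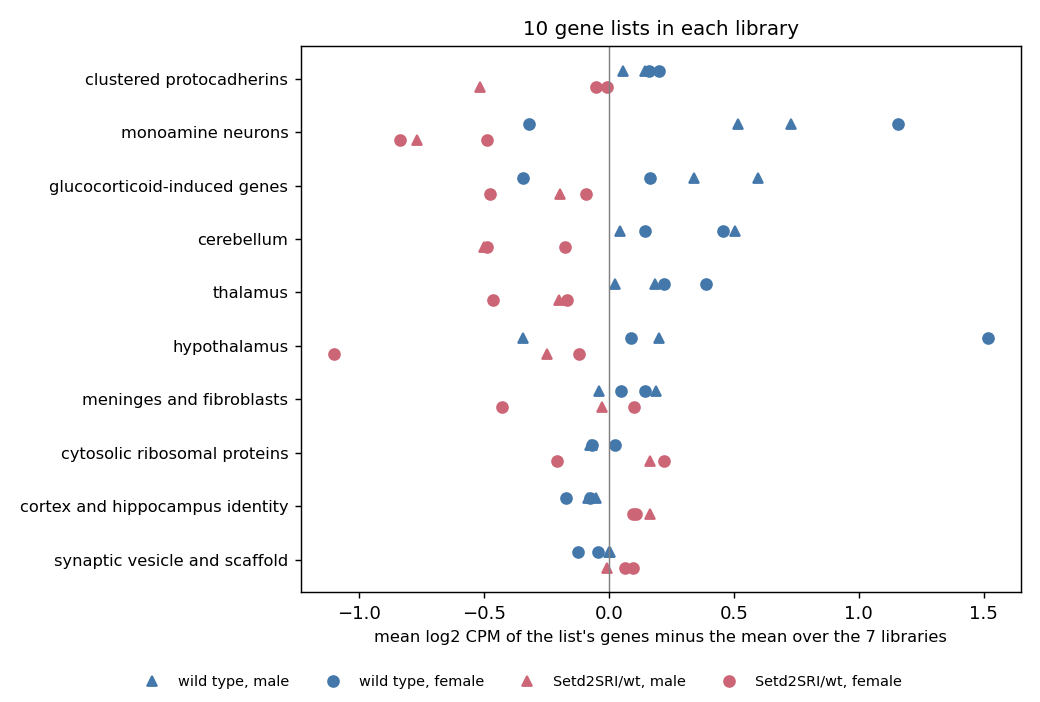
Mean log2 CPM of the genes of each of the 10 lists in each library, as the difference from the mean over the 7 libraries, with triangles for males, circles for females, blue for wild type and red for Setd2SRI/wt. For cerebellum the mutant libraries lie from -0.497 to -0.173 and the wild-type libraries from 0.046 to 0.506, while for hypothalamus wild-type female 2 stands alone at 1.516.

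Of the genes tied to the enzyme itself, the list of H3K36 methylation writers, erasers and readers had a median of -0.06 over 23 genes and did not pass (adjusted p = 0.547). Its member of smallest p, the mismatch repair gene Msh6, had a log2 fold change of -0.33 ± 0.13 (SE, adjusted p = 0.448). SETD2 is also known to methylate tubulin, and the tubulin list (median -0.05, adjusted p = 0.412) and the list of microtubule-associated proteins and motors (median -0.03, adjusted p = 0.75) did not pass. In each of these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone.

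Lists of glia, vessels and blood did not pass. All 11 microglia genes had positive fold changes (median 0.17, adjusted p = 0.0615), and 1, the fractalkine receptor gene Cx3cr1, passed adjusted over the list alone with 33.3 ± 0.776 CPM in wild type and 46.3 ± 7.99 CPM in the mutants. Adjusted p-values were 0.344 for astrocytes, 0.487 for the oligodendrocyte lineage, 0.609 for endothelial cells and pericytes, 0.609 for red blood cells and 0.689 for choroid plexus. Slc4a4 among the astrocyte genes and the glucose transporter gene Slc2a1 among the endothelial genes were lower adjusted over the list alone. Among neuronal lists adjusted p-values were 0.0882 for striatum, 0.924 for inhibitory neurons, 0.713 for glutamate receptors, 0.767 for GABA receptors, 0.767 for neural progenitors and 0.924 for stress hormone and serotonin signalling. Npy was higher and Calb2 lower among the inhibitory neuron genes, and Htr2c lower among the stress and serotonin genes, adjusted over the list alone.

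Lists of cell state did not pass either. Adjusted p-values were 0.304 for immediate-early genes, 0.623 for the hypoxia response, 0.924 for heat shock and the unfolded protein response, 0.924 for the interferon response, 0.782 for the cell cycle and 0.219 for steroid and cholesterol synthesis. They were 0.245 for mitochondrial transcripts, 0.713 for histone genes, 0.767 for skeletal muscle, skin and sensory epithelium, and 0.0882 for X-linked genes with known escape and Xist. In the hypoxia list Ddit4 and Slc2a1 were lower adjusted over the list alone. The mean of the mitochondrial list, -0.02, differed in sign from its median of 0.12, and for stress hormone and serotonin signalling the mean of -0.20 differed from the median of 0.07. For inhibitory neurons the median was -0.02 and the mean -0.03 while the test pointed upwards, and for the sensory list the median of 0.04 and the mean of -0.13 differed in sign. Pituitary hormones, small nucleolar RNAs and Y-linked genes had 4 tested genes each and hindbrain Hox genes 0, too few for the list test.

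The libraries differed in transcripts of neighbouring tissues. Hindbrain and spinal cord Hox genes summed to 491 counts in wild-type male 1 and to between 0 and 11 counts in each other library. The pituitary hormone genes Gh and Prl had 79 and 141 counts in wild-type female 2, 6 and 10 counts in Setd2SRI/wt female 1 and 0 to 6 counts in each other library. Pomc was at 12.7 CPM in wild-type female 2, 9.12 CPM in Setd2SRI/wt female 1 and between 1.005 and 1.625 CPM elsewhere. Omp, a gene of olfactory sensory neurons, was at 6.22 and 4.29 CPM in the wild-type males and at 0.361 to 0.853 CPM in the other 5 libraries. With wild-type female 2 and Setd2SRI/wt female 1 left out, an alternative chosen after seeing the data, 57 genes were called between genotypes, 25 higher and 32 lower, with Slc17a6, Ret and Robo3 among them.

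**Figure D3:**
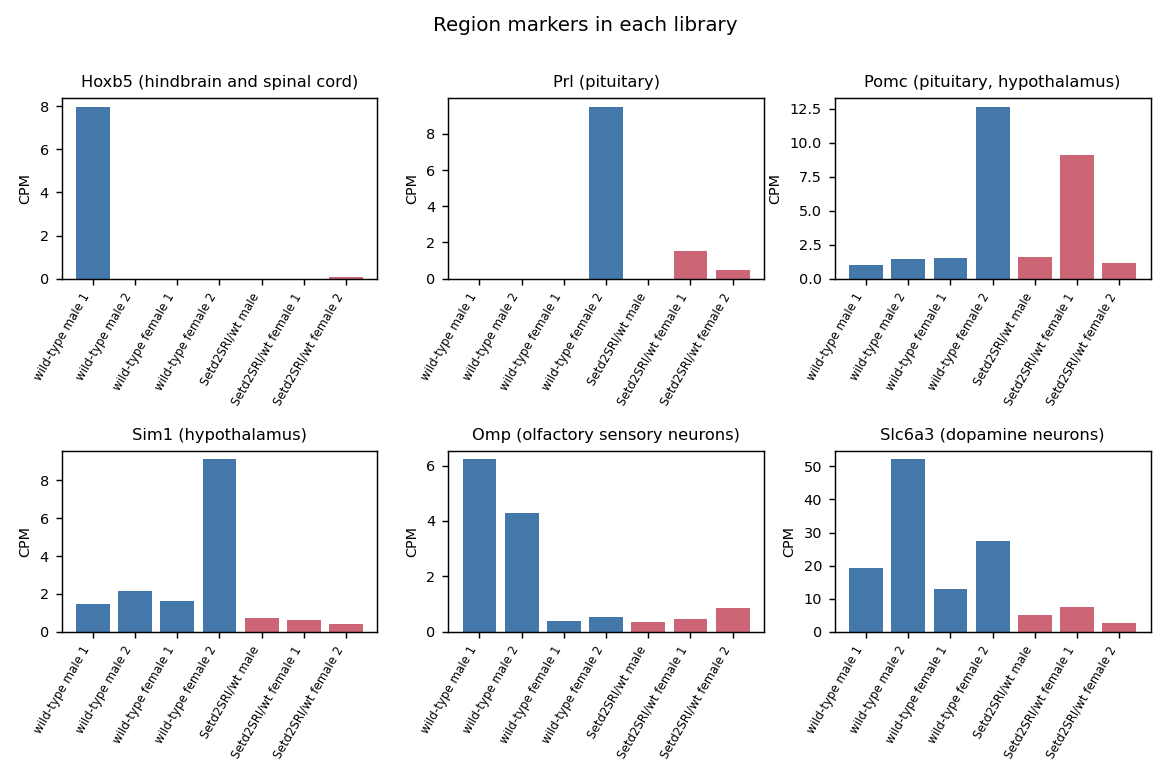
CPM of 6 marker genes in each library, with bars in blue for wild type and in red for Setd2SRI/wt. Hoxb5 reaches 7.97 CPM in wild-type male 1, Prl 9.50 CPM in wild-type female 2 and Omp 6.22 CPM in wild-type male 1, and Slc6a3 lies at or below 7.51 CPM in the mutants and at or above 12.9 CPM in wild type.

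The next comparison asked which genes differed between the sexes, and it also checked the sex labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d, Uty and Gm29650 were higher in males, and Xist, Eif2s3x and Ddx3x were lower in males. Xist, the RNA that silences one X chromosome in females, had 1212 ± 120 CPM (SD, n = 4) in females and 6.19 ± 3.85 CPM (SD, n = 3) in males, with a log2 fold change of -7.76 ± 0.24 (SE) and an adjusted p of 2.79e-12. Ddx3y, an RNA helicase gene, had 94.3 ± 8.11 CPM in males and 0.0469 ± 0.0937 CPM in females (adjusted p = 3.36e-13). Eif2s3x and Ddx3x, which escape X inactivation, had log2 fold changes of -0.96 ± 0.12 and -0.65 ± 0.10 (SE) in males against females, with adjusted p-values of 8.21e-04 and 0.0112. Every library had the Xist and Y-linked levels of its labelled sex.

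These 8 genes, 5 higher and 3 lower in males, were called among 17260, and 814 genes had an unadjusted p under 0.05. Of the Y-linked list, 4 genes were tested between the sexes and all 4 passed over all genes. Gm29650 is a lincRNA gene, and the count of Xist is uncertain because Xist overlaps Tsix. Prlr, the prolactin receptor gene of the choroid plexus, had 26.9 ± 10.1 CPM in females and 13.0 ± 1.79 CPM in males and did not pass (adjusted p = 0.0968). Without wild-type female 1, 20 genes were called, and without Setd2SRI/wt female 2, 14 genes. Ddx3x was lost without wild-type male 1, without wild-type male 2 or without the Setd2SRI/wt male.

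The list test was also applied to sex, which had not been planned. By camera, protocadherins (median -0.23, adjusted p = 2.89e-07), choroid plexus genes (median -0.69, adjusted p = 4.22e-06) and X-linked genes with known escape and Xist (median -0.48, adjusted p = 1.09e-10) were lower in males. The protocadherin score was -0.514 in the Setd2SRI/wt male but 0.144 and 0.059 in the wild-type males, against -0.05 to 0.201 in females. The choroid plexus score was -1.182 in wild-type male 1, -0.203 in the Setd2SRI/wt male and 0.158 in wild-type male 2, against 0.171 to 0.429 in females. In each of these lists 1 male library thus lay far below the other males. Glucocorticoid-induced genes (median 0.42, adjusted p = 0.00115) and heat shock and unfolded protein genes (median 0.13, adjusted p = 0.036) were higher in males. With an estimated correlation none of these 5 lists passed, with an adjusted p of 0.106 for the X-linked list and 0.9285 for each of the others.

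The last comparison asked whether the genotype difference depended on sex. edgeR called 0 of 18269 genes, with 632 at an unadjusted p under 0.05, DESeq2 called 2, Cdhr1 and Gm13340, and limma-voom 0. The smallest adjusted p, 0.0558, belonged to Gm13340, an unprocessed pseudogene named here because it ranked first. It had 226 and 235 CPM in the wild-type females and 49.5 to 83.4 CPM in the other 5 libraries. For Slc17a6, Ret and Robo3 the interaction had an adjusted p of 0.998. The mutant males were a single library, and its spread was taken to be that of the other groups.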

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

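The tests of depth, of shared protocadherin reads and of the Setd2SRI/wt male alone, all counts of splits, and the margin of 1 SE used to read the tests were chosen only after the results were seen. For the median of a list, that SE was taken over its genes as if they were independent. It does not measure the spread between animals. Of 100 values examined, 12 had a library far from the others of its group, while chance gives about 1 in 20, a rate that does not apply to Uty and Ddx3y, where the other libraries were at exactly 0. Wild-type male 2 had a total of 4.19 M counts, 22368 detected genes and 0.01219% haemoglobin counts, against 14.84 to 16.06 M, 27179 to 27411 genes and 0.007718 to 0.007806% in the other wild-type libraries. It also had 14.8 CPM of Col1a2, a collagen gene, against 16.19 to 16.25, and 9.04 CPM of Chrna6, a receptor gene of dopamine neurons, against 3.51 to 4.12. Wild-type male 1 had 491 counts of hindbrain Hox genes against 1 to 11. Wild-type female 2 had 9.10 CPM of Sim1 against 1.44 to 2.14, 14.9 CPM of Otp against 0.714 to 2.89, 5.17 CPM of Gh against 0 to 0.238 and 22.2 CPM of Robo3 against 29.2 to 30.2. Among the 4 females, wild-type female 1 had 0.0625 CPM of Uty and 0.187 CPM of Ddx3y, and the other 3 had 0.

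By camera with a preset correlation, the lists of monoamine neurons, thalamus, hypothalamus and cerebellum were lower in Setd2SRI/wt brains and the cortical identity list was higher, but with an estimated correlation none passed (adjusted p = 0.616, 0.707, 0.882, 0.4931 and 0.4931). Lower depth of the mutant libraries is argued against as the whole cause. After thinning to the shallowest library, 4 of the 4 lists still passed with a preset correlation. Their medians became smaller in size. They went from -1.46 to -1.33 for monoamine neurons, -0.77 to -0.52 for cerebellum, -0.41 to -0.29 for thalamus and -1.16 to -1.06 for hypothalamus. A part played by depth stays open. GC content and gene length are argued against as well. The median of the 37 members was -0.985 before a trend on both was removed and -1.02 ± 0.18 (SE over genes) after. A smaller share of midbrain and diencephalon tissue met the bound set for it. In lists not used before, 21 genes of these regions and the hindbrain had a median log2 fold change of -0.706 ± 0.30 (SE over genes). Of these genes, 20 were negative. The exact permutation p was 0.0286 for the midbrain and hindbrain genes and 0.286 for the diencephalon genes. On the latter, wild-type female 2 was highest at 0.816. These lists were chosen after seeing the data, and lower expression within the same tissue would meet the bound as well. A larger share of cortical neurons also met its bound, with a median of 0.161 ± 0.05 (SE over genes) over 19 genes. Between libraries this list did not separate the groups (exact permutation p = 0.0857). The Setd2SRI/wt male was at -0.024 and the wild-type libraries from -0.179 to -0.01. The share of tissue may differ through dissection or through a genotype difference in the size of these regions, and neither was tested here.

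Clustered protocadherins were lower in Setd2SRI/wt brains by camera with a preset correlation, and not with an estimated one (adjusted p = 0.4931). Reads shared between overlapping Pcdha and Pcdhg genes are argued against as the whole cause. The Pcdhb genes, which share no exons, had a median of -0.421 ± 0.09 (SE over genes), with 21 of 21 negative. The medians of the Pcdha and Pcdhg genes were -0.09 and -0.403. Without the Setd2SRI/wt male the median of the list was -0.226 ± 0.06 (SE over genes). This was too close to its bound to separate this library from the genotype, and a genotype difference stays open.

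Olfactory genes such as Omp were high in the wild-type males. S100a5 was at 5.401 CPM in wild-type male 1 and 4.055 CPM in wild-type male 2, and at most 0.388 CPM elsewhere. In the same order, Cdhr1 was at 21.602 and 44.37 CPM, and at most 12.005 CPM elsewhere. Doc2g was at 7.41 and 16.698 CPM, and at most 3.951 CPM elsewhere. These markers go with olfactory tissue in the wild-type male libraries but do not measure its share. The list test left olfactory tissue in these libraries open. On an olfactory list not used before, the lower wild-type male exceeded the highest other library by 0.287 on the log2 scale, between the bounds set. A difference between the sexes also stays open, since the value of the Setd2SRI/wt male minus the mean of the 4 females was -0.162 but rests on 1 mutant male.

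Of the 35 splits of the libraries 34 could be fitted, the counts of splits below include the real one, and the number of calls alone does not exclude chance for any of the counts below. For the 3 genes called between genotypes, 4 splits gave as many, and the highest other split gave 147. For the 7 lists lower in Setd2SRI/wt, 7 splits gave as many, and the highest other gave 10. Each of these 7 splits had Setd2SRI/wt female 2 in the group of 3, so this count depends on that library. For the 3 lists higher, 24 splits gave as many, and the highest other gave 11. For the 8 genes called between the sexes, 6 splits gave as many, and the highest other gave 104. That count says nothing against Xist and the Y-linked genes themselves, which separated all 7 libraries by labelled sex. The split with 147 genes calls many times the real count and points to a structure of the samples. For sex, the highest other split grouped wild-type male 1, wild-type male 2 and wild-type female 1. With genotype in the model it set them against wild-type female 2 alone, so its count rests on that library. The split with 147 genes set wild-type male 1, wild-type male 2 and wild-type female 2 against the other 4 libraries, so it differs from the genotype split by wild-type female 1 alone, and without that library the genotype comparison called 110 genes.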

How the results depend on the processing

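Thinning and the analysis without the libraries with pituitary transcripts were chosen after seeing the data. Of the alternatives for single genes, 1772 kept direction and side of the threshold, 123 became called, 32 lost their call and 3 reversed, and of those for the Setd2 fold change and for counts of genes or lists, 106 kept direction and side of the threshold or stayed within 1.5 times of the count, and 81 did not. The cause was not tested except where named. Genes changed between genotypes (3, with 1 higher and 2 lower) were 1 (0 and 1) with total counts, with a mean CPM of at least 1 and with limma-voom, 331 (56 and 275) with no filter, 65 (20 and 45) with DESeq2, and 5 (4 lower) at an adjusted p under 0.1, which by construction admits more. They were 0 (0 and 0) with no sex term, 1 (0 and 1) in females without a block, 80 (6 and 74, Slc17a6, Ret and Robo3 among them) in females with a replicate block, and 57 (25 and 32) without the libraries with pituitary transcripts. Leaving out each library gave 0 to 110 (0 to 11 higher, 0 to 99 lower). Genes changed between the sexes (8) were 136 (46 higher, 90 lower) with no filter and 15 (11 higher) in wild type only, and 8 to 20 (5 to 9 higher, 3 to 15 lower) leaving out each library. Interaction genes (0 in edgeR, 632 at an unadjusted p under 0.05, limma-voom 0) were 1 with TMM without abundant classes, 21 with no filter, 2 with DESeq2, 2 at an adjusted p under 0.1 and 1 to 4 leaving out each library; without the only mutant male the interaction could not be fitted. Lists (3 higher, 7 lower) were 0 and 0 with an estimated correlation and with directional fry, 2 lower with mixed fry, 5 higher with no sex term, 1 higher in females with or without a block, 1 higher and 11 lower without the libraries with pituitary transcripts, and 1 to 5 higher leaving out each library. The genotype log2 fold change of Omp (-1.10) reversed to 0.66 without the Setd2SRI/wt male and ran from -2.51 to 0.66 leaving out each library. That of Eif2s3y (0.38) reversed to -0.24 without that male, ran from -0.24 to 0.41 leaving out each library, and was -0.22 with no sex term; for this Y-linked gene the mutant group without that male holds only females. Across genes, the difference between female 1 and female 2 in wild type correlated at -0.0576 with the same difference in Setd2SRI/wt. This is a single contrast, so it cannot tell whether the numbers pair the animals. After thinning to 4192021 counts 14393 genes were tested and the 3 genotype genes were kept, while the meninges and synaptic lists lost their calls and the cerebellum median was -0.52 over 5 genes. With robust dispersion the count stayed at 3, with Irx2 in place of Ret. The cortex list lost its call in females with a replicate block (adjusted p = 0.0804).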

Other observations

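The tests of imprinted genes and of the clock were chosen only after the results were seen, and all gene lists in this part were chosen after seeing the data. Midbrain and hindbrain regulators had a median log2 fold change of -0.757 over 14 genes, 13 of them negative, with an exact permutation p of 0.0286, the smallest possible here (adjusted p = 3.94e-05 by camera, and adjusted p = 0.0522 with an estimated correlation). In this list 0 genes passed over all genes and 3 adjusted over the list alone, Slc6a5, Lhx5 and Gata3. Slc6a5, a glycine transporter gene, was at 41.8 CPM in wild-type male 1, the library with 491 Hox counts, at 13.1 CPM in wild-type female 2 and at most 0.952 CPM in the other 5 libraries. Lhx5 had 2.67 ± 0.981 CPM (SD, n = 4) in wild type and 0.986 ± 0.313 CPM (SD, n = 3) in the mutants. Hypothalamus and diencephalon regulators had a median of -0.706 over 7 genes, all negative (adjusted p = 0.00691 by camera, exact p = 0.286, adjusted p = 0.279 with an estimated correlation), with Foxb1 among those lower adjusted over the list alone. Wild-type female 2 stood alone on this list at 0.816. The other wild-type libraries, at -0.254 to 0.185, overlapped the mutants, at -0.524 to 0.008. Cortical neuron genes had a median of 0.161 over 19 genes (adjusted p = 0.00345 by camera, exact p = 0.0857, adjusted p = 0.29 with an estimated correlation), with Crym and Lmo4 higher adjusted over the list alone. Lmo4 had 139 ± 7.92 and 180.2 ± 4.39 CPM. On the olfactory list 1 gene, Stoml3, was lower adjusted over the list alone (median -0.155, exact p = 0.171, adjusted p = 0.502 with an estimated correlation).

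Zdbf2, an imprinted gene, stood among the smallest p-values, and the hypothesis was that imprinted genes were lower as a class. Their median was -0.216 over 34 genes, with 0 passing over all genes and 13 lower adjusted over the list alone, among them Zdbf2, Peg10, Zim1, Dlk1 and Magel2. By camera with a preset correlation the adjusted p was 1.13e-04. The exact p was 0.171 and the adjusted p with an estimated correlation was 0.279, so the hypothesis stays open. Wild-type female 2 had the highest score of this list, 0.475, and also of the hypothalamus list, 1.516.

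A difference in clock phase was tested because Per1 stood among the glucocorticoid-induced genes. The median absolute log2 fold change of 15 clock genes was 0.151, with Per1 lower and Npas2 higher adjusted over the list alone. The exact p of 0.486 belongs to the signed mean list difference, in which opposite changes cancel. It therefore cannot test a shift in phase, and the question stays open. A dependence of the genotype difference on gene length gave a Spearman rho of -0.154 across genes (exact p = 0.314). Antisense and pseudogene transcripts, 1060 genes, had a median of 0.0706 (exact p = 0.257). Both hypotheses stay open. The choroid plexus score was -1.182 in wild-type male 1 and between -0.203 and 0.429 in the other 6 libraries. The mitochondrial gene mt-Nd4l was at 64.8 CPM in wild-type female 1 and between 3.34 and 22.9 CPM in the other 6 libraries.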
